A study of Lytechinus variegatus with 64 samples.

How the data were processed

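PolyA RNA from tissues, gonads and eggs of the sea urchin Lytechinus variegatus was sequenced as 64 bulk libraries. Adult tissues and eggs were prepared by one sequencing provider and gonads of juveniles aged 4.5 months post fertilization by another, so age and provider cannot be separated in any comparison between juvenile and adult libraries. STAR, featureCounts and DESeq2 are named in the submitters' processing notes, without versions. The genome build was not given in the sources used here. The deposited values are raw counts of reads per gene, in 1 table with a column for each library, and nothing in the table was normalized. Of the lines in the table, 3 were left out because their fields were broken or displaced. One of them carried counts in 61 of the 64 columns with no gene name of its own. The remaining 25887 genes were used, and all of them matched symbols in a RefSeq table of assembly Lvar_3.0, which was used only for biotype, gene span and which genes neighbour each other.

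The table identifies genes by locus identifiers, apart from 74 transfer RNA and mitochondrial RNA rows, and neither it nor the RefSeq table pairs the identifiers with product names. The 18 lists of known gene groups that had been fixed beforehand therefore matched 0 genes, and no gene set test was run. Genes are reported by identifier. Mitochondrial protein genes were not analysed here. Reads shared between near-identical gene copies, or between overlapping genes, could be split by the counting, and no strand setting was given in the sources used here, so values of such genes are uncertain.

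Groups followed the labels. The 14 adult sample types with 3 or 4 libraries each (53 libraries) entered the tests, together with the 3 libraries of juvenile gonads of indeterminate sex. Coelomic fluid, the 4 spine types, the stage 1 ovary, the juvenile ovary and the juvenile testis had 1 library each and were described without a test. The labels do not say whether replicates came from separate animals, so p-values measure only the spread between these libraries, which may be technical. No pair of libraries held identical counts.

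Differential expression was tested on the deposited counts with edgeR 4.0.16 (glmQLFit and glmQLFTest, limma 3.58.1, R 4.3.3), with TMM scaling and the filterByExpr filter. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. The atlas comparison used 1 fit of the 53 adult libraries and set each type against the mean of the other 13. The 6 comparisons of 2 groups were each fitted on the libraries of those groups alone. Standard errors of log2 fold changes were taken from the fold change and its F statistic. Library-size scaled counts (CPM) were TMM-scaled over all 64 libraries. Tissue-specific genes had a mean of at least 10 CPM in a type, lay at least 4-fold (with 0.5 CPM added) above the mean of each other adult type, and had every library above every library of the other types. For coelomic fluid a gene needed 100 CPM and an 8-fold excess over each adult mean. For a spine it needed 10 CPM and an 8-fold excess over each other spine. In the juvenile libraries a gene needed 10 CPM on the higher side and a 4-fold gap between all 3 indeterminate libraries and both sexed libraries. Medians over sets of genes were placed among 10000 random lists of the same size matched on mean expression.

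At most 2 rising and 2 falling identifiers are named per comparison, those with the largest fold change among genes that were called, reached 10 CPM on the higher side and showed no overlap between the libraries compared. Atlas genes had to lie above every library of every other type. Where the lower group had 0 counts, the fold is a lower bound against 3 counts in its shallowest library.

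Other settings chosen beforehand were DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, no filter, each replicate left out, the replicate number as a block, 1 fit over all replicated groups, a rest without eggs, ovary and testis, glmTreat against a fold of 2, and other thresholds and pseudocounts for the descriptive rules. Fits without the adult ovary, or with eggs in its place, were added after the data had been seen. The designs, the naming rule and those other settings were fixed before the data were examined.

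Library totals ran from 13113913 to 59521125 counts, with a median of 26099257. The 95% Wilson intervals of the shares of counts given for gonad gene sets were no wider than 0.0205 percentage points on either side. They cover counting error only. The tests were run on simulated data drawn from the real means, library sizes and fitted spread, with 200 changed genes. In the simulation of the indeterminate gonad against the testis, on 19709 genes, 1.43% of genes changed by 1.5 on the log2 scale were recovered, 48.6% of those changed by 3 and 83.3% of those changed by 6. For the indeterminate gonad against the ovary, on 15042 genes, the shares were 0%, 17.1% and 76.7%. For the testis against the ovary, on 14332 genes, the shares were 4.29%, 57.1% and 80%. For the tube foot against the other adult types, on 19138 genes, they were 12.9%, 75.7% and 90%. The adjusted p depends on how many genes change, and 55.9% of genes were called in the real testis and ovary comparison. Shares recovered with 200 changed genes therefore need not hold for the real comparisons.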

Results

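The atlas measured polyA transcripts in 14 adult sample types with 3 or 4 libraries, in juvenile gonads at 4.5 months post fertilization and in several types with 1 library. Axial gland, eggs, esophagus, gut, interambulacral plates, lantern muscle, ovary, radial canal, radial nerve, testis and tube foot had 4 libraries each. Mouth, peristomial membrane and rectum had 3. The lantern is the jaw apparatus of the animal, and the peristomial membrane is the soft skin around the mouth. Totals ran from 13113913 counts in esophagus replicate 3 to 59521125 in the stage 1 ovary.

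The number of genes at 1 CPM or more was lowest in the adult ovary, with 12423 ± 616 (SD, n = 4). It was 15110 ± 388 in eggs (n = 4) and 17167 ± 1358 in testis (n = 4). Gut had 13814 ± 1660 genes (n = 4), and in gut replicate 2 the 10 most abundant genes took 46.4% of all counts. Across genes, the profile of interambulacral plates was closest to that of the peristomial membrane (Spearman rho 0.956), and lantern muscle was closest to the radial canal (0.948). Genes are not independent replicates, so these coefficients describe the libraries. The adult ovary was the most distant of all types from most others, and its nearest type, the eggs, reached only 0.870. The stage 1 ovary library (rho 0.934 with eggs) and the juvenile ovary library (0.935 with eggs) lay closer to eggs than the adult ovary did.

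**Figure D1:**
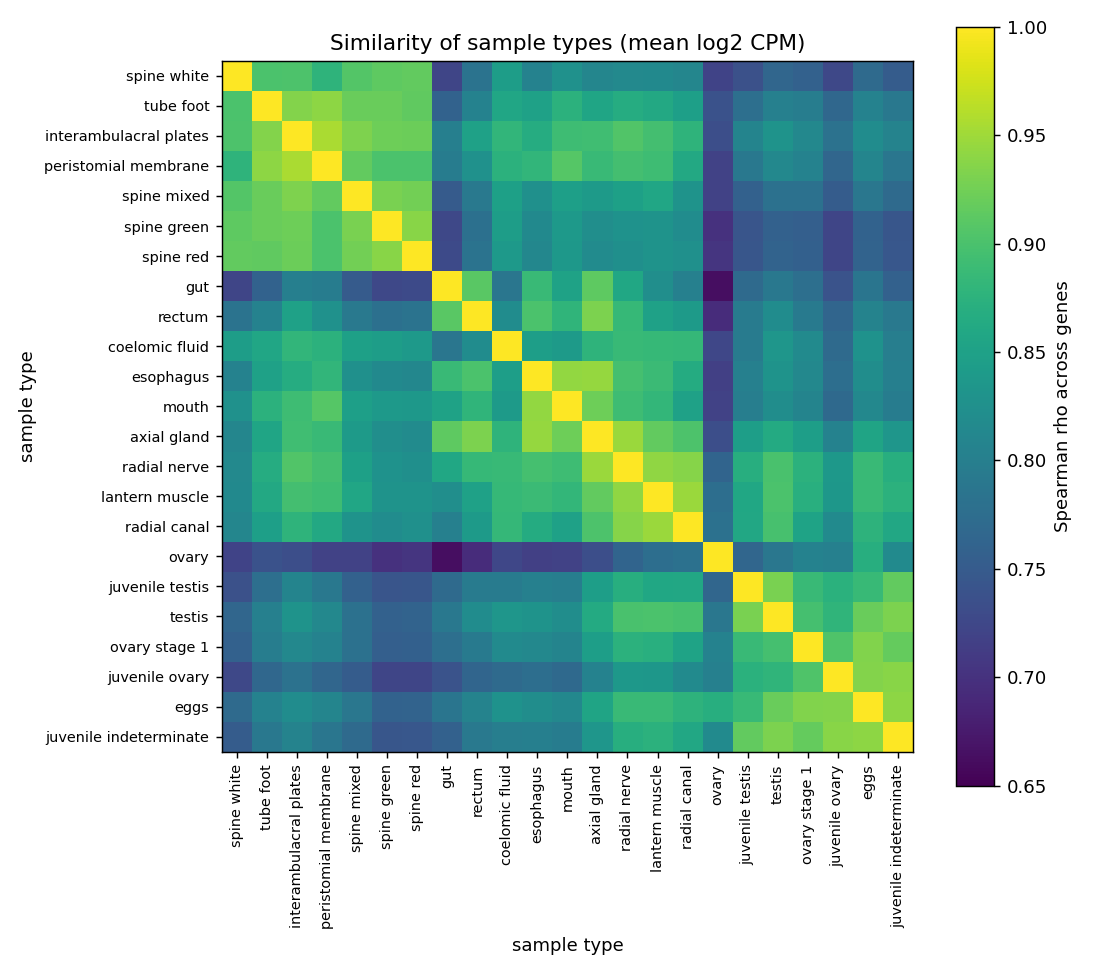
Spearman correlation across genes between the mean log2 CPM profiles of all 23 sample types, on both axes, with colour from 0.65 to 1. The adult ovary stands apart, with 0.870 to its nearest type and 0.663 to the gut.

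To find what sets each adult tissue apart, each type was compared with the mean of the other 13 over 23383 genes. The ovary had 5860 genes called higher and 7924 lower, and its median log2 fold change over all tested genes was -1.003. TMM scaling assumes that most genes do not differ, so its lower calls are relative to that scaling. They may include a shift over all genes. Eggs had 4557 higher and 1894 lower, testis 4320 and 1405, and gut 4212 and 3368. Tube foot followed with 3766 higher and 1034 lower, interambulacral plates with 3277 and 467, radial canal with 3013 and 1127, axial gland with 2896 and 290, and esophagus with 2892 and 930. Peristomial membrane had 2826 higher and 702 lower, rectum 2780 and 717, mouth 2160 and 280, radial nerve 1962 and 288, and lantern muscle 1630 and 619. Against a fold of 2 by glmTreat the higher calls fell by over 1.5 times in 12 of the 14 types, and the DESeq2 Wald test moved the balance of higher and lower calls, for example to 1284 higher and 1871 lower in lantern muscle. Leaving out 1 library of the type itself moved the lower calls by over 1.5 times in 12 types. Libraries of the other types were not left out in turn. Axial gland had 191 lower genes without replicate 1 and 138 without replicate 3, eggs 1182 without replicate 4, and esophagus 428 without replicate 3. Interambulacral plates had 192 without replicate 2 and 275 without replicate 3. Lantern muscle had 254, 268, 407 and 261 without each replicate in turn, and mouth 106, 93 and 141. Peristomial membrane had 370 without replicate 1 and 137 without replicate 2, where its higher calls fell to 1881. Radial canal had 682 without replicate 3, and radial nerve 158 without replicate 2 and 134 without replicate 3. Rectum had 162, 447 and 366 without each replicate in turn, testis 723 without replicate 1, and tube foot 675 without replicate 1.

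The genes named for each type had the largest fold changes among those above every library of the other types. In tube foot, LOC121413943 reached 12923 ± 8132 CPM (SD, n = 4) and LOC121413940 8802 ± 3845, with log2 fold changes of 14.96 ± 0.84 (SE) and 13.56 ± 0.83. In mouth, LOC121417283 had 27493 ± 8111 CPM (n = 3) and LOC121417672 18039 ± 5407, with log2 fold changes of 15.16 ± 0.84 and 14.89 ± 0.80. In interambulacral plates, LOC121424524 had 5258 ± 2765 CPM (n = 4) and LOC121419866 2475 ± 2008, while no library of the other 13 replicated types exceeded 21.1 CPM for the first. The spines, with 1 library each, were not part of that comparison. They had 4515 CPM of the first gene in the green, 5351 in the mixed, 2800 in the red and 130 in the white. Without plate replicate 3 the mean of the second gene was 1636 CPM. In eggs, LOC121408951 had 29868 ± 19133 CPM (n = 4) and LOC446158 24513 ± 13189. Among the other 13 replicated types, the highest library reached 4286 CPM for the first, in radial nerve replicate 2. The stage 1 ovary and the juvenile ovary, with 1 library each, were not part of that comparison. They had 17445 and 15296 CPM of the first gene, above the lowest egg library with 5831. In rectum, LOC121415619 had 11310 ± 4286 CPM (n = 3) and LOC121406976 had 277 ± 152. In radial canal, LOC121406130 had 7881 ± 4517 CPM (n = 4) and LOC121412219 had 94.2 ± 48.9. The separation of the first was narrow, with 3136 CPM in the lowest radial canal library against 2740 in a library of another replicated type. In the ovary, LOC121423180 had 10641 ± 1890 CPM (n = 4) and LOC121430376 had 662 ± 77.1. The lowest adult ovary libraries had 8781 and 571 CPM. The stage 1 ovary had only 39.9 and 2.50 CPM of these genes, and the juvenile ovary 419 and 106. Both genes thus marked these adult ovary libraries and not every ovary library. Libraries of other replicated types reached 1476 CPM for LOC121413943, 946 for LOC121417283, 2619 for LOC121415619 and 3056 for LOC121423180.

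The same rule gave less abundant genes in the other types, up to 647 CPM on average. Gut had LOC121422071 at 647 ± 589 CPM (SD, n = 4) and LOC121430626 at 595 ± 419. Peristomial membrane had LOC121427752 at 608 ± 252 CPM (n = 3) and LOC121406527 at 192 ± 272. For LOC121406527 its lowest library had 6.61 CPM, against 6.56 in the highest library of another replicated type. Lantern muscle had LOC121424550 at 532 ± 637 CPM (n = 4) and LOC121409221 at 11.2 ± 5.56. Testis had LOC121422812 at 245 ± 318 CPM (n = 4) and LOC121419675 at 206 ± 295, with 646 CPM in testis replicate 1. Radial nerve had LOC121425491 at 123 ± 91.2 CPM (n = 4) and LOC121406007 at 46.7 ± 29.2. Esophagus had LOC121431967 at 58.7 ± 72.7 CPM (n = 4) and LOC121425927 at 47.8 ± 32.7, with 96.4 CPM in esophagus replicate 2. Without the highest library, means fell by over 1.5 times for 8 of these 12 genes. LOC121406527 fell to 35.4 CPM without peristomial membrane replicate 1 (log2 fold change 8.05 against 10.59), LOC121422071 to 389 without gut replicate 2, and LOC121424550 to 235 without lantern muscle replicate 3. LOC121422812 fell to 92.8 and LOC121419675 to 59.4 without testis replicate 1, and LOC121425491 to 79.1 without radial nerve replicate 1. LOC121431967 fell to 23.6 without esophagus replicate 3 and LOC121425927 to 31.6 without replicate 2. No axial gland gene lay above every library of the other types. The edgeR adjusted p of the genes named for single types ran from 4.76e-21 for LOC121419866 to 6.48e-10 for LOC121409221.

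Tissue-specific genes were most numerous in the ovary, with 1058, and then in gut with 198, testis with 112, tube foot with 81, eggs with 58 and mouth with 56. Radial canal had 28, rectum 26, interambulacral plates 20, esophagus 10, peristomial membrane 8, radial nerve 7 and lantern muscle 6. These sets are specific among the 14 replicated types, and types with 1 library were not used to choose them. The plate set took 1.34% of counts in the green spine, 1.37% in the mixed, 0.655% in the red and 0.0781% in the white, against 0.640% to 1.97% in the plates. The tube foot set took 0.947% to 1.36% in the 4 spines. The axial gland had 0, and without its replicate 1 it had 1. The ovary set took 43.7% ± 3.11 of counts in the ovary (SD, n = 4), the egg set 13.98% ± 5.41 in eggs (n = 4) and the mouth set 11.1% ± 3.16 in mouth (n = 3). The tube foot set took 6.44% ± 1.20 (n = 4), the gut set 5.71% ± 2.23 (n = 4) and the testis set 1.43% ± 1.45 (n = 4). An 8-fold margin left 164 ovary genes. Leaving out testis replicate 3 raised the testis count to 243, leaving out radial nerve replicate 1 raised the nerve count to 21, and leaving out lantern muscle replicate 4 raised the muscle count to 31. The rectum count was 56 without rectum replicate 2 and 52 without replicate 3. Eggs had 96 without eggs replicate 1, and esophagus had 16 without esophagus replicate 2. Among adult libraries of other types, axial gland libraries held the most counts in 3 sets. These were 0.702% in the gut set in replicate 3 (median of all such libraries 0.101%), 0.340% in the rectum set in replicate 1 (0.00431%) and 0.0153% in the esophagus set in replicate 3 (0.000245%).

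**Figure D2:**
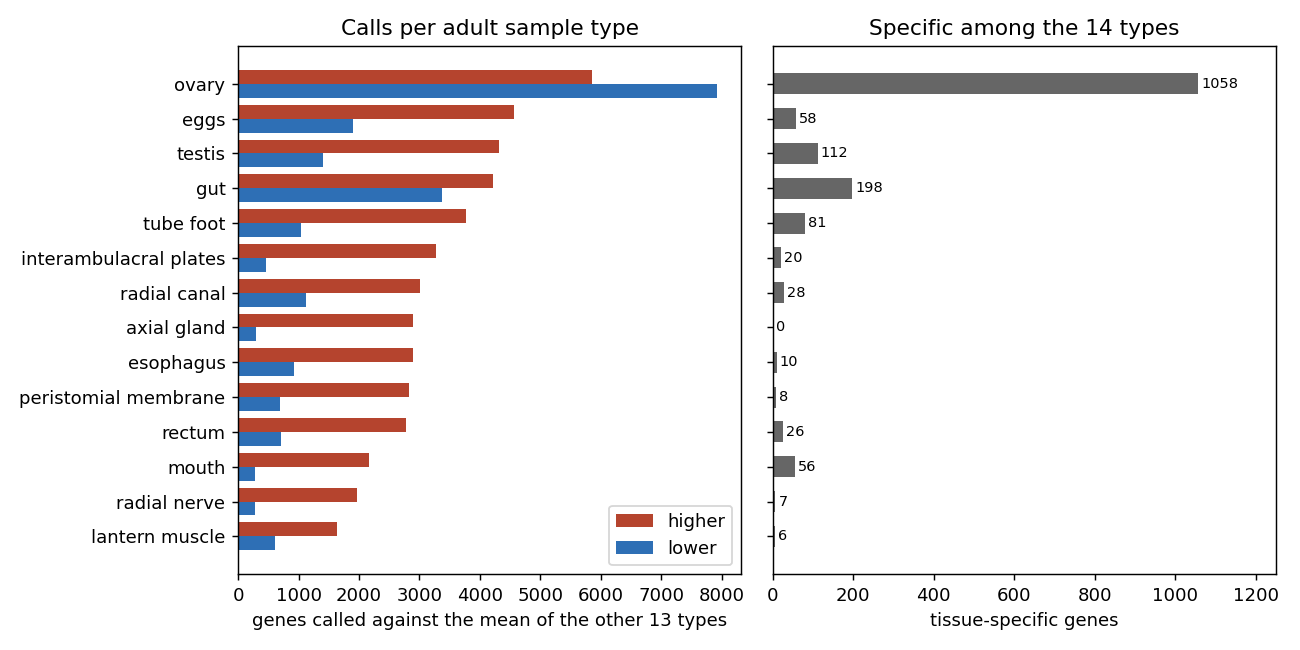
Left, genes called higher or lower in each of the 14 adult types against the mean of the other 13 (bars, number of genes); right, genes specific to 1 type among those 14, spines not considered. The ovary has the most of each, with 5860 higher, 7924 lower and 1058 specific genes.

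The adult testis and ovary were compared for the sex difference of the gonad. Of 17715 genes, 5730 were called higher in testis and 4166 lower. These calls cannot be read as a sex difference alone, since the adult ovary also stood apart from eggs and the other ovary libraries. Among 2544 genes at 10 CPM or more in every other library, 447 lay at least 4-fold above the median of those libraries in the ovary. Another 700 lay at least 4-fold below it. Reads from another organism in the ovary were not excluded. LOC121423429 had 850 ± 1084 CPM in testis (SD, n = 4) and LOC121419675 had 206 ± 295, both with 0 counts in the ovary, so they were at least 5756-fold and 1395-fold higher. Testis replicate 1 carried much of both means, and without it the bounds were 2208-fold and 402-fold. LOC121423180 had 10641 ± 1890 CPM in ovary (n = 4) against 2.29 ± 1.35 in testis (n = 4), a log2 fold change of -12.09 ± 0.70 (SE, edgeR adjusted p = 1.80e-05). LOC121413637 had 289 ± 130 CPM in ovary against 0.0762 ± 0.117, with a log2 fold change of -11.62 ± 1.07 (edgeR adjusted p = 4.11e-05). With eggs in place of the adult ovary, a choice made after seeing the data, 517 genes were higher and 784 lower in testis.

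Eggs were compared with the adult ovary, the organ that makes them. Of 16877 genes, 4635 were higher in eggs and 3759 lower. LOC121408450 had 41.4 ± 14.1 CPM in eggs (SD, n = 4) and LOC121412188 had 36.4 ± 40.01, against 0 counts in the ovary, at least 280-fold and 246-fold higher. Without eggs replicate 4 the bound for LOC121412188 was 119-fold. LOC121420606 had 14.9 ± 14.4 CPM in the ovary (n = 4) against 0.585 ± 0.612 in eggs (n = 4), a log2 fold change of -4.62 ± 0.99 (SE, edgeR adjusted p = 0.00421). LOC121416555 had 19.2 ± 24.4 against 0.622 ± 0.585 CPM, a log2 fold change of -4.61 ± 1.19 (edgeR adjusted p = 0.00924), and ovary replicate 4 held the highest value. Without the highest ovary library the means were 7.87 CPM for LOC121420606 (replicate 2) and 7.11 for LOC121416555. Without eggs replicate 2 the lower calls numbered 2494.

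Juvenile gonads of indeterminate sex were compared with each adult gonad. Against the ovary, 4574 of 18417 genes were higher and 3428 lower. LOC121423111 had 136 ± 228 CPM in the indeterminate gonads (SD, n = 3) and 0 counts in the ovary, at least 922-fold higher, and at least 32.0-fold without replicate 1. LOC121428833 had 2646 ± 4573 CPM against 0.0759 ± 0.152 (n = 4). Without indeterminate replicate 3 its mean was 5.49 CPM and its log2 fold change fell from 14.88 to 6.04. For both genes the SD exceeded the mean, the lowest indeterminate library had 3.97 and 5.23 CPM, and DESeq2 gave no adjusted p. LOC121407133 had 130 ± 85.7 CPM in the ovary (n = 4) and 0 counts in the indeterminate gonads, at least 1721-fold lower there. LOC121407213 had 80.3 ± 71.0 CPM against 0.0554 ± 0.0960, with the highest values of both genes in ovary replicate 4, a log2 fold change of -10.37 ± 1.43 (SE, edgeR adjusted p = 6.94e-04). Without that library the mean of LOC121407213 was 45.04 CPM. With eggs in place of the ovary, chosen after seeing the data, edgeR called 0 genes in either direction. Age and sequencing provider cannot be told apart in these comparisons.

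Against the testis, edgeR called 0 of 20521 genes in either direction, while 3135 had an unadjusted p under 0.05 and the lowest adjusted p was 0.122. DESeq2 called 610 genes higher and 843 lower, and 1 edgeR fit over all replicated groups called 394 and 420. Without indeterminate replicate 1, edgeR called 69 higher and 8 lower. As a result the main edgeR fits called 0 genes on the same side of both adult gonads. The edgeR fit over all replicated groups called 192 higher and 184 lower than both, and DESeq2 called 298 and 181. Without indeterminate replicate 1, edgeR called 37 genes higher than both.

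The juvenile libraries came from 1 provider and were compared without a test. The testis-specific set took 1.63% of counts in indeterminate replicate 1, 0.141% in replicate 2 and 0.107% in replicate 3, against 1.17% in the juvenile testis and 0.0507% in the juvenile ovary. The egg-specific set took 0.230%, 6.06% and 3.27% in the same 3 indeterminate libraries, 0.385% in the juvenile testis and 10.6% in the juvenile ovary. The ovary-specific set took between 4.49% and 7.28% in all 5 juvenile libraries, far below its share in the adult ovary. In adult libraries of the other replicated types its median was 2.97%, and the highest was 11.2% in eggs replicate 3. Between the juvenile testis and the juvenile ovary, the median log2 ratio was 3.21 for the testis set, above all 10000 random lists, and -5.01 for the egg set, below all of them. Of 6176 genes called between adult testis and ovary and reaching 10 CPM in a sexed juvenile library, 53.4% differed in the same direction between those libraries, while 50.3% of all genes at that level were higher in the juvenile testis. With the adult calls taken against eggs, chosen after seeing the data, 95.04% of 988 genes did. Both shares count any difference, however small. Among genes called between adult testis and ovary and at least 4-fold apart in the sexed juvenile libraries, 959 went in the adult direction and 436 in the opposite one. For the calls against eggs these numbers were 643 and 6.

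No gene lay 4-fold above both sexed juvenile libraries in all 3 indeterminate libraries, and 9 lay 4-fold below. LOC121411287 had 1.54, 2.44 and 0.402 CPM in the indeterminate libraries against 28.7 in the juvenile ovary and 62.4 in the juvenile testis. LOC121423546 had 2.04, 2.52 and 5.38 CPM against 46.3 and 85.9. Without indeterminate replicate 3 the lower count was 58, and with 5 CPM added it was 3.

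**Figure D3:**
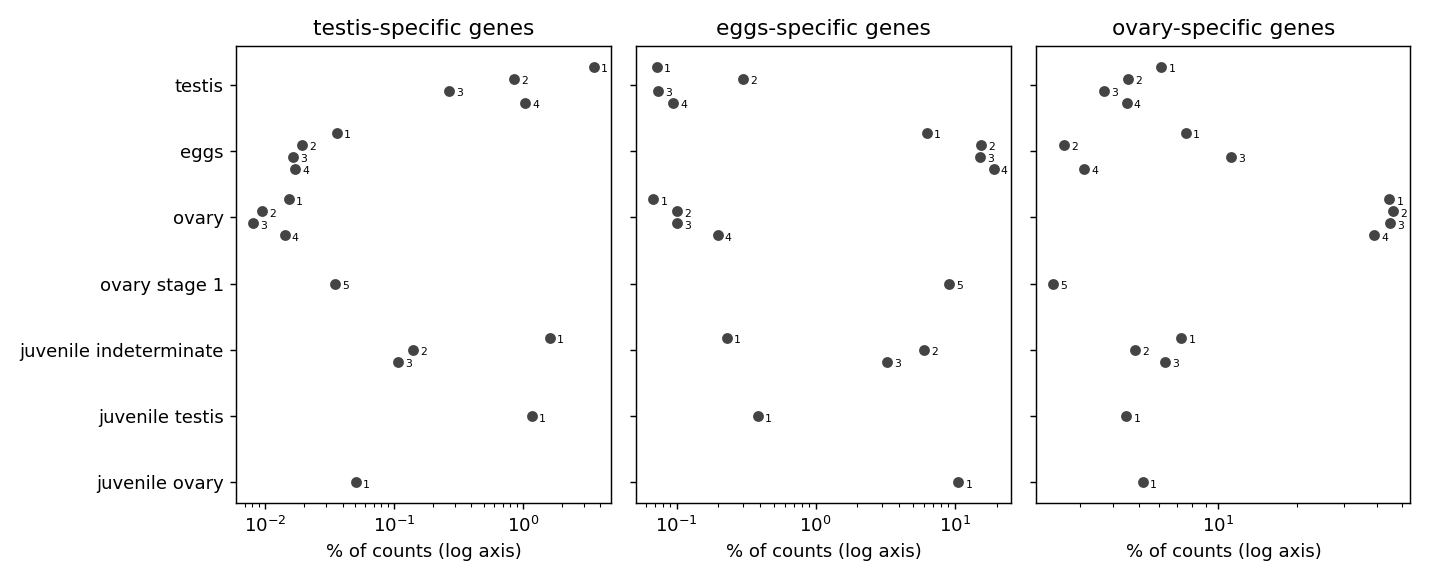
Share of all counts (percent, log axis) taken by the testis-specific, egg-specific and ovary-specific genes in each gonad and egg library, with points numbered by replicate. Indeterminate replicate 1 has 1.63% in the testis set, and replicates 2 and 3 have 6.06% and 3.27% in the egg set.

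Along the digestive tract, gut was compared with esophagus and rectum. Against esophagus, 836 of 17133 genes were higher in gut and 579 lower. LOC121412641 had 466 ± 225 CPM in gut (SD, n = 4) and LOC121423029 had 139 ± 119, with 0 counts in esophagus, at least 1398-fold and 418-fold higher. Without esophagus replicate 3, the shallowest library, the bounds were 2796-fold and 836-fold, and without gut replicate 3 the second was 271-fold. LOC121425927 and LOC121431967 had 0 counts in gut and were at least 100-fold and 123-fold lower there. The bounds were 310-fold and 380-fold without gut replicate 2. That of LOC121425927 was 66.2-fold without esophagus replicate 2, and that of LOC121431967 was 49.3-fold without esophagus replicate 3. The lower count was 193 without gut replicate 1, and DESeq2 called 1378 genes higher and 1437 lower.

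Against rectum, 349 of 17719 genes were higher in gut and 309 lower. LOC121425067 had 530 ± 377 CPM in gut (SD, n = 4) against 0.153 ± 0.152 in rectum (n = 3), a log2 fold change of 11.72 ± 1.33 (SE, edgeR adjusted p = 0.0155). LOC121419107 had 432 ± 573 CPM in gut against 2 counts in all rectum libraries, a ratio of 16401 with a counting interval of 4540 to 135424. The ratio was 5799 without gut replicate 1 and 10732 without rectum replicate 3, and without rectum replicate 2, which held both counts, it was at least 3446. LOC121431359 had 667 ± 449 CPM in rectum (n = 3) against 0.159 ± 0.319 in gut (n = 4), and LOC121424985 had 88.5 ± 26.1 in rectum against 2 counts in gut. Without the highest library the means were 347 CPM for LOC121425067 and 153 for LOC121419107 (gut replicate 1), and 431 for LOC121431359 (rectum replicate 3). LOC121419107 and LOC121431359 lost their calls without gut replicate 1, without gut replicate 3 or without rectum replicate 3, and LOC121425067 without rectum replicate 3 (log2 fold change 12.66, edgeR adjusted p = 0.0515). LOC121419107 also lost its call without rectum replicate 1 or 2. The log2 fold changes stayed large in these fits, from 12.24 to 16.07 for LOC121419107 and from -12.28 to -12.19 for LOC121431359, with edgeR adjusted p from 0.0551 to 0.116. The counts fell with almost any library left out, to 19, 30 and 26 higher and 9, 15 and 7 lower genes without gut replicates 1, 2 and 3. They fell to 61, 128 and 13 higher and 52, 45 and 7 lower without rectum replicates 1, 2 and 3. Without gut replicate 4 they rose to 452 higher and 567 lower, and that library held 0.173% of counts in the rectum-specific genes, against 0.00768% to 0.0195% in the other gut libraries. DESeq2 called 1389 higher and 1221 lower.

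Coelomic fluid, the fluid of the body cavity, had 35 genes at 100 CPM or more and at least 8-fold above every adult mean. LOC121423247 reached 794 CPM, 34.7-fold above its next type, the rectum, and LOC121425233 reached 787 CPM, 31.4-fold above the radial canal. Among the spines, the mixed library had 72 genes 8-fold above each other spine, the green one 24, the white one 21 and the red one 17. LOC121421728 had 281 CPM in the mixed spines against 2.43 in the next spine, and LOC121420740 had 199 CPM in the green against 2.40. LOC121412855 had 109 CPM in the white against 0.0357, and LOC121410331 had 25.1 CPM in the red against 0.143. With 5 CPM added the counts were 26 in mixed, 6 in green, 3 in white and 2 in red. In the stage 1 ovary the egg set took 9.04% of counts and the ovary set 2.38%. The medians of these sets in adult libraries of the other replicated types were 0.0504% and 2.97%. These types had 1 library each, so differences have no replicate check.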

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

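All tests of explanations in this part were chosen, or their bounds written down, after the values they use had been seen, except the positions of the indeterminate libraries between the sexed juvenile libraries and the relabelled draws of the atlas. In groups of 4, a library far from the other 3 turned up in 15 distinct groups of values, over 111 tests. Genes named in more than 1 comparison were tested each time but counted once. For independent, normally spread values chance gives about 1 in 20. Many of these values share libraries and need not be normal, so an excess over chance was not established.

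The adult ovary libraries stood apart from every other type, including eggs, the stage 1 ovary and the juvenile ovary. Lower depth is argued against: after thinning to 10000000 counts the ovary library with the most genes at 10 counts had 13426, below the lowest egg library with 14797. Gene span explained 3.65% of the variance of the eggs minus ovary fold changes. Reads from another organism or a distant strain cannot be told apart from biology by the test made. Among 2544 genes found in every other library, those high in the ovary lay 0.74 (log2, 95% interval 0.55 to 0.87) above those low in it when eggs were set against somatic tissues, between the bounds for either outcome, and the stage of the adult ovary stays open and untested.

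Axial gland replicate 2 was nearest to radial nerve replicate 1 (Spearman rho 0.953) and not to its own type, as 14 libraries of replicated types were nearest to a library of another type. The same library deposited a second time is argued against, since 70.8% of genes at 10 CPM or more differed by over 3 Poisson standard errors. A radial nerve sample labelled axial gland could not be decided. In 19 nerve genes chosen without it, replicate 2 had 27.5% of the mean share of radial nerve replicates 2 to 4, between the other axial gland libraries, held out in the same way (4.06% to 14.9%), and the nerve replicates 2 to 4 (36.9% to 291%). Radial nerve replicate 1 had 22.5%. In a second measure, over 60 genes that separate the other libraries, replicate 2 had a median position of 0.23 between nerve (0) and axial gland (1). That measure failed on libraries not in doubt, since axial gland replicate 1, held out, came to -0.01 and radial nerve replicate 4 to 0.67. No biological explanation was tested.

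The 3 indeterminate juvenile libraries differed from each other in the testis and egg sets. Carry-over of adult somatic tissue into the same gonad tissue is argued against as the whole cause, since it would lower both sets together. Allowing for the highest shares in any adult somatic library (0.0522% for the testis set and 2.77% for the egg set), the shared tissue would need an egg to testis ratio of at most 0.146 from replicate 1 and at least 4.65 from replicates 2 and 3. Juvenile somatic tissue was not analysed here, and the share of somatic tissue-specific genes, from 0.273% to 0.322%, lay within those of the juvenile ovary (0.240%) and testis (0.355%). A hypothesis is that germ cells of 1 sex may already be present. Over 471 other genes that separate adult testis from eggs and also both sexed juvenile libraries, the median position between juvenile ovary (0) and juvenile testis (1) was 0.75 in replicate 1 (bootstrap interval 0.65 to 0.82), 0.25 in replicate 2 (0.21 to 0.27) and 0.36 in replicate 3 (0.31 to 0.41). The bounds of 0.25 and 0.75 were crossed by the intervals of replicates 1 and 2, and the position of replicate 3 lay between the bounds. A middle position had been set beforehand to count against the hypothesis, which was wrong: the genes were picked for a gap between 2 single libraries, and that pulls any other library towards the middle. Replicate 3 also had 3.27% of counts in the egg set against 0.385% in the juvenile testis, with 57 of 58 egg genes higher than there (median log2 ratio 2.99). Against the juvenile ovary it went the other way, with 5 of 58 egg genes higher (median log2 ratio -2.05). Of 112 testis genes, 78 were higher in replicate 3 than in the juvenile ovary (median log2 ratio 0.71). The hypothesis stays open for all 3 libraries. The intervals were added after the positions were seen. Each position rests on 1 library between 2 single libraries, so its interval can cover only the spread over genes. Genes are not independent replicates, and the spread between libraries is left out.

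Gut replicate 2 had 46.4% of counts in its 10 most abundant genes, against 17.6% to 22.5% in the other gut libraries. Interambulacral plate replicate 1 had 32268962 counts against 23398585 to 24849127, and replicate 4 had 1.14% of counts in mitochondrial RNA rows against 0.597% to 0.658%. Radial nerve replicate 1 had 19.2% in its 10 most abundant genes against 14.03% to 14.9%, and 0.0950% in nerve-specific genes against 0.0453% to 0.0522%. Those genes had to be high in this library to be chosen, and without it the set grew to 21. In the 19 nerve genes chosen without axial gland replicate 2, radial nerve replicate 1 had only 22.5% of the mean share of replicates 2 to 4. The higher share therefore does not show that it was richer in nerve transcripts. Radial nerve replicate 2 had 2.77% of counts in egg-specific genes against 0.0338% to 0.0757% in the other nerve libraries. Testis replicate 2 had 0.302% in egg-specific genes against 0.0718% to 0.0947%. Tube foot replicate 4 had 16023 genes at 1 CPM against 16981 to 17130, and 1.47% in mitochondrial RNA rows against 0.439% to 0.580%. Esophagus replicate 4 had 0.0735% in esophagus-specific genes against 0.0445% to 0.0466%, a set chosen with these same libraries. Single genes far from the rest of their group were LOC121425927 at 96.4 CPM in esophagus replicate 2, LOC121419675 at 646 CPM in testis replicate 1, and LOC121416555 at 55.5, LOC121407133 at 258 and LOC121407213 at 186 CPM in ovary replicate 4. A displaced line of the table that names no gene held 124470 counts in all and was not used.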

How the results depend on the processing

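Fits without the adult ovary or with eggs in its place were chosen after seeing the data; the other settings were planned. The cause of each move was not tested, except where fewer libraries or a stricter rule made it. DESeq2 size factors in edgeR kept all counts that answer a comparison within 1.5 times. Without a filter 755 genes were lower in interambulacral plates, and the other such counts stayed within 1.5 times. No named gene reversed in any setting run. The size factors shifted the median log2 fold change by -0.13 in eggs, 0.14 in gut and -0.13 in ovary, and by 0.15 in testis minus ovary and 0.14 in indeterminate minus ovary. Both scalings assume that most genes do not differ, so neither checks for a shift over all genes in the ovary. Depth sets the level below which a group with 0 counts cannot be told from a low one: 3 counts in the shallowest library came to 0.148 CPM in the ovary. Simulated changes of 1.5 (log2) were recovered in 0% to 12.9% of genes, and neither depth nor the number of changed genes was varied there. In 20 simulations of unchanged groups edgeR called 0 genes on the same side of both adult gonads, which says nothing beside a real count of 0. Gene lists matched no identifiers, so none of their alternatives was run.

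By glmTreat against a fold of 2, higher calls were 1494 in axial gland, 2497 in eggs, 1379 in esophagus, 2732 in gut, 1865 in interambulacral plates, 670 in lantern muscle, 1239 in mouth, 1577 in peristomial membrane, 1352 in radial canal, 823 in radial nerve, 1793 in rectum and 2309 in testis. Lower calls were 72 in axial gland, 728 in eggs, 142 in esophagus, 1537 in gut, 54 in interambulacral plates, 134 in lantern muscle, 56 in mouth, 81 in peristomial membrane, 411 in radial canal, 43 in radial nerve, 218 in rectum, 448 in testis and 350 in tube foot. It gave 2171 genes lower in eggs than ovary, 505 higher and 190 lower in gut than esophagus, and 64 higher and 27 lower in gut than rectum. With a rest without eggs, ovary and testis, higher calls were 1701 in axial gland, 1900 in esophagus and 1431 in mouth, and lower calls were 132 in axial gland, 483 in esophagus, 1190 in lantern muscle, 156 in mouth, 297 in peristomial membrane and 1782 in radial canal. One fit over all replicated groups called 7083 genes higher in eggs than ovary, 8172 higher in indeterminate gonads than ovary, 394 higher and 420 lower in them than testis, 192 higher and 184 lower than both, 1526 lower in gut than esophagus, and 585 higher and 1258 lower in gut than rectum. DESeq2 called 610 higher and 843 lower in indeterminate gonads than testis, 298 higher and 181 lower than both gonads, 1378 and 1437 in gut against esophagus, and 1389 and 1221 in gut against rectum. In the atlas it called lower 762 genes in axial gland, 3379 in eggs, 1432 in esophagus, 776 in interambulacral plates, 1871 in lantern muscle, 904 in mouth, 1290 in peristomial membrane, 2462 in radial canal, 762 in radial nerve, 1654 in rectum, 2259 in testis and 1625 in tube foot. With eggs in place of the adult ovary, testis had 517 higher and 784 lower genes, indeterminate gonads had 0 and 0, and 95.04% of genes differed in the adult direction in the juveniles. Without the adult ovary eggs had 120 specific genes and 2867 lower ones, and axial gland had 189 lower ones.

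An 8-fold margin left 5 specific genes in esophagus, 128 in gut, 11 in interambulacral plates, 3 in lantern muscle, 164 in ovary, 5 in peristomial membrane, 5 in radial canal, 3 in radial nerve, 15 in rectum and 48 in tube foot. With 5 CPM added, 3 genes lay below both sexed juvenile libraries, and the spine counts were 6 in green, 26 in mixed, 2 in red and 3 in white.

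With 1 library left out at a time, counts ran from 1881 to 2054 for genes higher in peristomial membrane, 2494 to 3700 for lower in eggs than ovary, 193 to 810 for lower in gut than esophagus, and 13 to 452 higher and 7 to 567 lower in gut than rectum. In the atlas and for specific genes, only libraries of the type itself were left out. For genes beyond both adult gonads or both sexed juvenile libraries, only indeterminate libraries were. Lower calls in the atlas ran from 138 to 235 in axial gland, 1182 to 1628 in eggs, 428 to 882 in esophagus, 192 to 416 in interambulacral plates, 254 to 407 in lantern muscle, 93 to 141 in mouth, 137 to 530 in peristomial membrane, 682 to 1092 in radial canal, 134 to 338 in radial nerve, 162 to 447 in rectum, 723 to 1551 in testis and 675 to 829 in tube foot. Against testis, indeterminate gonads had 0 to 69 higher and 0 to 8 lower, and 0 to 37 genes lay above both adult gonads. Juvenile counts ran from 0 to 7 above and 18 to 58 below both sexed libraries. Specific genes ran from 0 to 1 in axial gland, 52 to 96 in eggs, 11 to 16 in esophagus, 6 to 31 in lantern muscle, 7 to 21 in radial nerve, 34 to 56 in rectum and 83 to 243 in testis.

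With the replicate number as a block (replicate block), indeterminate gonads had 2 genes higher and 8 lower than testis, and 2 higher than both gonads; other counts stayed within 1.5 times. LOC121419107 lost its call in gut minus rectum (log2 fold change 12.40, edgeR adjusted p = 0.0622). The numbers did not meet the rule for pairing: same-numbered eggs and ovary libraries deviated together with correlations from 0.0936 to 0.331, and 3 of 4 pairs were over 0.1. All 8 of those libraries correlated best with their own number, a hint from the data and not from the design.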

Other observations

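The test on neighbouring genes was chosen after the tissue-specific genes were known. The bounds for the splits of 2 groups, and the counts over sets of libraries, were also chosen after the results were seen. Long non-coding RNA genes took 9.11% ± 3.30 of counts in rectum (SD, n = 3), 8.41% ± 2.19 in radial canal (n = 4) and 7.81% ± 1.03 in esophagus (n = 4). They took 2.56% ± 0.513 in eggs (n = 4) and 1.61% ± 0.165 in the adult ovary (n = 4). Of the genes called higher in testis than in the mean of the other adult types, 8.82% were long non-coding. For the ovary the share was 4.85%. Esophagus (8.64%), gut (8.40%), radial canal (8.33%) and lantern muscle (8.22%) lay close to testis, and mouth (4.95%) lay close to the ovary. In the direct comparison of testis with ovary, 5.71% of the genes higher in testis were long non-coding. These differences were not tested, and the share among all tested genes is not given here.

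Tissue-specific genes of one tissue lay next to each other in the annotation more often than random genes at 10 CPM or more in that tissue, which were not matched further on level. The 198 gut genes held 27 adjacent pairs, against a mean of 2.08 and a highest value of 10 in 10000 random draws. The 81 tube foot genes held 11 pairs (mean 0.328), the 56 mouth genes 6 (mean 0.160), the 26 rectum genes 5 (mean 0.0342) and the 112 testis genes 8 (mean 0.703). For these 5 tissues p was 0.0001, the smallest such draws can give, and 0.0001 after Benjamini-Hochberg adjustment over the 9 sets of at least 20 genes. The ovary set held 87 pairs against a mean of 60.4 and a highest of 89 (adjusted p = 0.0007). Neighbouring genes may share regulation in a tissue, or may be recent copies of one another that share reads, which was not tested.

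Chance was tested by other splits of the same libraries. For testis and ovary, 1 of 35 splits, the real one, gave as many genes (9896, highest other 0). The same held for eggs and ovary (8394, highest other 0) and for indeterminate and ovary (8002, highest other 1168). It also held for gut and esophagus (1415, highest other 0) and for gut and rectum (658, highest other 31). That argues against chance in each comparison taken alone. Since 1 of 35 is the smallest share such splits can give, chance is not excluded over all of these comparisons. For indeterminate and testis the real count was 0 and the highest other 0, so all 35 splits had to give as many and the test says nothing. In the atlas, 25 draws of the labels were used, the real one included. This test is weak, since the draws were few and mixed groups gave up to 4546 higher genes. The real labels gave the most higher genes for axial gland (2896, highest other 1074), eggs (4557, 1506), esophagus (2892, 2632), gut (4212, 1579), lantern muscle (1630, 1231), ovary (5860, 1313), peristomial membrane (2826, 1144), radial canal (3013, 1078), rectum (2780, 1501) and tube foot (3766, 3344). Chance could not be excluded this way for interambulacral plates (3277, highest other 3416, 2 draws as large), mouth (2160, 3194, 2 draws), radial nerve (1962, 2677, 3 draws) and testis (4320, 4546, 2 draws). For those 4 types, genes at 10 CPM or more with every library of the type above all other adult libraries were counted, and the same count was made for every set of as many libraries. Interambulacral plates had 27 such genes, and 37 of 292825 sets had as many. Radial nerve had 18 (60 sets) and testis 130 (4 sets), and the highest other set was the adult ovary with 1943. Mouth had 83, and 15 of 23426 sets of 3 had as many, the highest other being 3 ovary libraries with 875. Few sets held as many genes, but sets of mixed types reached 83 genes with 4 libraries and 92 with 3. Those lay above interambulacral plates, radial nerve and mouth, and below testis. The count was chosen after the results were seen and repeats the separation rule used to name genes, so it does not exclude chance.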
